A study of Homo sapiens with 8 samples.

How the data were processed

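RNA sequencing was done on tumours grown in mice from T24, an established human bladder cancer cell line, with or without enforced expression of the receptor gene DDR1. The labels gave 8 libraries, 4 control and 4 DDR1, and each library was put in its group by its condition label. Replicate numbers 1 to 4 followed accession order and only name a library. The labels do not say that the libraries came from separate animals. DDR1 replicates 2, 3 and 4 share a title prefix, so the DDR1 group holds only 2 prefixes, and control replicates 3 and 4 share another. The tests treat all 8 libraries as independent, so p-values measure only the spread between these libraries, which may be technical in part.

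Per the labels' protocols, RNA was taken from homogenised tumours with a column kit, messenger RNA was selected on poly-T beads, fragmented and copied from random hexamers, and the libraries were sequenced as paired ends of 150 bp. The protocols do not mention strand marking. Per the submitters' processing notes, the tools were FastQC 0.11.9, Trim Galore 0.6.4, STAR 2.7.5 and RSEM 1.3.1, and the build was GRCh38. The annotation release, any removal of mouse reads, and the settings of these tools are not given in the sources used here. Reads from mouse cells of the tumour can align to conserved human genes, and they then add to the values of those genes.

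Per the submitters' notes, the deposited expected counts are estimated counts per gene from RSEM, after alignment with STAR. That table held 58302 genes; 26.5% of the values above 0 were not whole numbers, and 15597 genes had 0 in every library. The expected counts were rounded to whole numbers before every count test. The authors also deposited TMM-normalized values, which are already on a log2 scale: for genes with counts above 100, value minus log2 count had a standard deviation of at most 0.00508 within a library. The log2 table held 22480 genes, each above 0 in all 8 libraries, while 20 further genes above 0 in all 8 libraries were not in it. The 8 files of single libraries held values identical to those of the log2 table and were not used further. An alternative fixed in advance had assumed linear values and an added 1 before taking logs. Because the deposited values were already log2, limma-trend was run on them as they stand.

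Gene identifiers were matched to GENCODE release 29, which is on the same GRCh38 build, and 58039 of the 58302 matched. The remaining 263 kept their identifiers as names. Coordinates are 1-based and come from that release. Where the authors' counting could split reads between copies or overlapping genes, values are uncertain. This holds for ribosomal protein genes, which have many processed pseudogenes, for HLA genes, for keratin genes, and for the 23 of the 61 named genes that overlapped another tested gene, 9 of them on the same strand and 14 on the other.

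Totals per library ran from 13716285 to 32271016 expected counts, so counting error was small beside the spread between libraries for all but the lowest genes. No pair of libraries agreed within counting error (lowest chi-square per degree of freedom 30.7), and none was counted as a duplicate. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 18973 genes, and libraries were scaled by TMM. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) of DDR1 against control over all 8 libraries with no covariate. Benjamini-Hochberg adjusted p-values under 0.05 were called. Levels are CPM scaled by TMM, and log2 CPM used a prior count of 2. The targeted gene DDR1 was also compared with an exact two-sided permutation test of log2 CPM, and its own unadjusted p decided its call because it was chosen in advance.

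Before the data were examined, 34 gene lists were fixed for tumour programs, other cell types and RNA quality. Lists with at least 5 tested members, 32 in all, were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The same step fixed the rule for named genes. It took DDR1 and DDR2, the 10 largest called changes in each direction with no overlap between groups and at least 5 CPM in the higher group, up to 4 members with the smallest p-values from each called list, and the most abundant member of each list of other cells. The part on called changes named 0 genes, and the rule named 61 genes in all. Any further gene named was chosen after its values were seen.

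The alternatives fixed in advance were 2 other scalings, DESeq2 1.42.0, limma-voom, limma-trend, no filter or a filter of 5 CPM in 4 libraries, leaving out each library, leaving out the controls with or without a lane in the title, summing libraries that share a title prefix, leaving DDR1 and mitochondrial genes out of library sizes, and the other set tests. Protein-coding genes only and limma-voom with library quality weights were added after seeing the data. All DDR1 titles name lane 8, while 2 control titles name lane 7 and 2 name no lane, so lane could not be a covariate. Each lane named in a title holds libraries of 1 group, and no within-lane comparison could be made. The 2 controls without a lane are also the 2 controls that share a title prefix. Leaving them out therefore does not separate lane from prefix.

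The pipeline was tested on simulated counts for the 18973 genes in 4 libraries against 4, with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 9% of the 2-fold and 54% of the 4-fold changes, with 2 false calls. A list shifted by -0.80 on the log2 scale was called. In 20 simulations without any change, 3 had at least 1 list called, at most 4. The simulated genes were drawn independently, while the median estimated correlation between genes of the real lists was 0.249. The simulated list calls therefore do not show how often correlated lists are called without a change.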

Results

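The data describe xenograft tumours of T24, a human bladder cancer line, grown from cells with enforced expression of DDR1 or from control cells. DDR1 is a receptor tyrosine kinase that is activated by collagen. Expression was measured by RNA sequencing, with poly-T selection per the protocol, in 4 control and 4 DDR1 libraries. The libraries held 19421530 ± 4198268 expected counts in the controls and 27678687 ± 5214337 in the DDR1 group (SD, n = 4 each). The difference in depth did not pass an exact two-sided permutation test (p = 0.0857). Although the protocol names poly-T selection, small RNAs made by RNA polymerase III, RMRP among them, took a large share of the counts. It was 11.7% ± 3.39 in controls and 8.77% ± 1.67 in DDR1 libraries (SD, n = 4, exact permutation p = 0.2). Libraries of 1 group were no more alike than libraries of different groups: the median correlation of log2 CPM across genes, which are not independent replicates, was 0.944 within and 0.944 between groups. The leading principal component held 33.4% of the variance and did not separate the groups. Levels below are means ± SD of TMM-scaled CPM over 4 libraries per group.

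The question of the design is what enforced DDR1 expression changes in these tumours, and the level of DDR1 itself checks the labels. DDR1 (ENSG00000204580, GRCh38 chromosome 6, 30876421 to 30900156, plus strand) stood at 152 ± 42.3 CPM in controls and 435 ± 274 CPM in the DDR1 group, a 2.86-fold higher level. Its log2 fold change was 1.52 with a standard error of 0.43 and an unadjusted edgeR quasi-likelihood p of 0.00612, which is 0.0122 adjusted over DDR1 and DDR2 and 0.9998 adjusted over all genes. The exact two-sided permutation test of its log2 CPM gave p = 0.0571, where 0.0286 is the smallest value that 70 orderings allow. The controls lay between 110 and 210 CPM, and 3 DDR1 libraries at 343, 427 and 810 CPM. The library labelled DDR1 replicate 1 held 159 CPM, inside the control range, so its DDR1 level does not bear out its label. Without the 2 controls of lane 7 the log2 fold change was 1.31 and the call was lost, with an unadjusted edgeR p of 0.0653 and an exact two-sided permutation p of 0.267, where 0.0667 is the smallest that 15 orderings allow. DDR2, the related collagen receptor (ENSG00000162733, chromosome 1, 162631373 to 162787400, plus strand), held 2.42 ± 0.926 CPM in controls and 1.86 ± 0.713 CPM in the DDR1 group. Its log2 fold change of -0.38 had a standard error of 0.37 and did not pass (unadjusted p = 0.334). The list of discoidin and collagen receptors, which contains DDR1, had a median of 0.17 over 10 members and did not pass as a set (camera adjusted p = 0.0786). It passed without control replicate 4 (0.0261), without DDR1 replicate 4 (0.0166) and without the library labelled DDR1 replicate 1 (0.00146). Its median was -0.57 without DDR1 replicate 3 (0.691) and 0.03 without control replicate 3 (0.395).

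**Figure D1:**
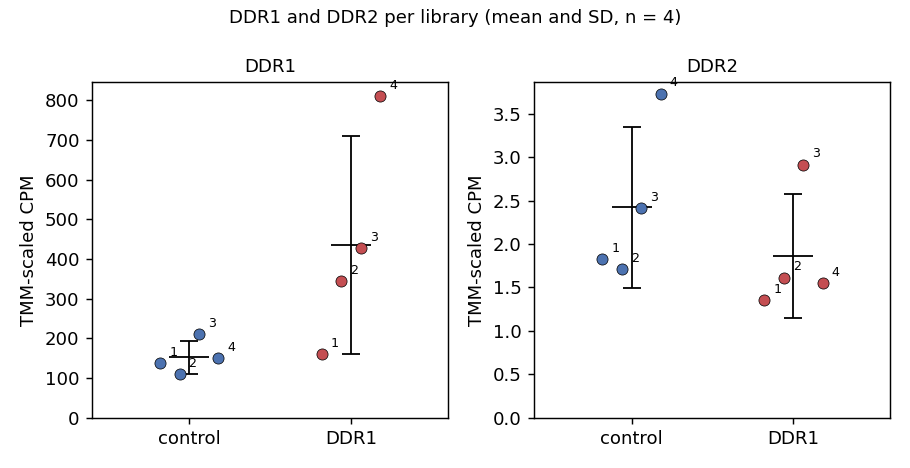
DDR1 and DDR2 in each library, in TMM-scaled CPM on a linear axis from 0, with replicate numbers beside the points and the mean and SD of 4 libraries as bars. The library labelled DDR1 replicate 1 lies at 159 CPM, below the highest control at 210 CPM.

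Of 18973 genes tested with edgeR, 0 passed at an adjusted p under 0.05, DDR1 included, and 791 (4.17%) had an unadjusted p under 0.05, 366 higher and 425 lower in the DDR1 group. limma-voom and limma-trend called 0 genes, and DESeq2 called 16, of which 8 were higher and 8 lower. The biological coefficient of variation was 0.386. The groups did not overlap for 456 genes, 2.40% of those tested, where chance gives 2.86%. Among the DESeq2 calls, named after their values were seen except for IL1B, were ANXA10, an annexin (1.92 ± 0.883 CPM in controls, 18.6 ± 15.4 in the DDR1 group), LGALS3, galectin 3 (29 ± 3.42 and 57.8 ± 10.6), PELI2 (8.03 ± 0.854 and 21.4 ± 8.53), MXRA5 (0.534 ± 0.431 and 7.05 ± 6.43) and RPS6KA5 (20.1 ± 1.14 and 40.1 ± 11.8). Calls in the other direction included the actin-bundling gene LCP1 (153 ± 17.2 and 47.1 ± 20.4), SLC12A8 (2.82 ± 0.879 and 0.665 ± 0.141), PTPN7 (4.61 ± 3.6 and 0.507 ± 0.259), CD83 (19.4 ± 7.44 and 6.63 ± 2.18) and IL1B. Each of these had an adjusted p of 0.9998 in edgeR's quasi-likelihood test.

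Of 32 gene lists, 13 passed camera with the preset correlation at an adjusted p under 0.05, 8 of them lower and 5 higher in the DDR1 group. None of the 32 passed when the correlation between genes was estimated from the data (smallest adjusted p = 0.430 with an estimated correlation), and none passed fry (smallest adjusted p = 0.440). The count of 13 was 8 without control replicate 4 and 6 without the 2 controls that have no lane. Those 2 controls also share a title prefix, so the lower count cannot be put down to lane. With edgeR no member of any list passed over all genes, and 1 member, IL1B, passed when adjusted over the list alone; with DESeq2 IL1B passed over all genes (adjusted p = 0.0495). All 3 lists fixed as signs of RNA quality (ribosomal proteins, mitochondrially encoded genes, handling stress genes) were among the 5 higher lists. RNA quality was therefore not separated from the group for the lists described below. The highest mean log2 CPM lay in control replicate 2 for mitochondrially encoded genes (9.74). It lay in DDR1 replicate 4 for ribosomal proteins (9.02) and handling stress genes (5.77).

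NF-kB targets and inflammatory cytokines fell as a list in the DDR1 group, with 18 of 20 members lower, a median log2 fold change of -0.81 and 10 members at an unadjusted p under 0.05 (camera adjusted p = 4.49e-12, and adjusted p = 0.430 with an estimated correlation). IL1B, an inflammatory cytokine (ENSG00000125538, chromosome 2, 112829751 to 112836903, minus strand), was 45.2 ± 21.2 CPM in controls and 16.9 ± 4.62 in the DDR1 group. Its log2 fold change was -1.42 with a standard error of 0.32, and it was the 1 member that passed when adjusted over the list alone (edgeR, adjusted p = 0.0295). That adjustment was not corrected over the 32 tested lists, so 1 such pass can arise by chance. Over all genes the edgeR adjusted p of IL1B was 0.9998. RELB, an NF-kB subunit, held 12.9 ± 3.61 and 6.64 ± 1.28 CPM in controls and the DDR1 group. BIRC3, an inhibitor of apoptosis, held 33.5 ± 15.8 and 12.6 ± 5.23 CPM, and IL32 held 5.27 ± 2.19 and 1.57 ± 1.07 CPM. These 3 had an edgeR p of 0.0513 adjusted over the list alone. Without the library labelled DDR1 replicate 1 the median was -0.53 and the list still passed. Neutrophil chemoattractants and myeloid growth factors also fell as a list, with 11 of 13 members lower, a median of -0.64 and 0 members passing alone (camera adjusted p = 3.87e-07, and adjusted p = 0.505 with an estimated correlation). CSF2, the growth factor GM-CSF, had a log2 fold change of -1.67 (5.29 ± 2.91 to 1.66 ± 0.688 CPM). CSF1 had -1.12, CXCL8 -0.98 and CXCL1 -0.75, and CXCL8 stood at 65.3 ± 26.1 and 33.2 ± 11.8 CPM. The median of this list was -0.41 without the library labelled DDR1 replicate 1 and -1.24 without DDR1 replicate 2. The call was lost without the 2 controls of lane 7 (adjusted p = 0.0636, median -0.42), and the median was -0.9995 without the 2 that have no lane.

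Interferon response genes fell as a list, with all 29 tested members lower, a median of -0.74 and 2 members at an unadjusted p under 0.05 (camera adjusted p = 9.74e-15, and adjusted p = 0.541 with an estimated correlation). OASL had a log2 fold change of -1.12 (39.5 ± 18.3 to 18.2 ± 7.39 CPM), USP18 -1.09, the transcription factor IRF7 -0.87 and DHX58 -0.61. The median shrank to -0.43 without control replicate 3 and -0.44 without DDR1 replicate 4, and to -0.19 without the 2 controls that have no lane, and was -1.13 without the 2 of lane 7; the list passed in each case. Antigen presentation genes fell as a list, with 17 of 19 members lower, a median of -0.20 and 0 members passing (camera adjusted p = 0.00604, and adjusted p = 0.631 with an estimated correlation). CD74, the invariant chain, had -0.72 (68.2 ± 25.1 to 41.3 ± 9.95 CPM), HLA-B -0.76, HLA-C -0.42 and the peptide transporter gene TAP2 -0.40. HLA-B and HLA-C have overlapping gene models and near-identical sequence, so their counts are uncertain. The call was lost without control replicate 4 (adjusted p = 0.120, median -0.12), DDR1 replicate 3 (0.104) and the 2 controls that have no lane (0.327, median -0.06), and with libraries of a shared title prefix summed (0.399). Without the library labelled DDR1 replicate 1 the median was -0.38. T cell chemokines and checkpoint ligands fell as a list, with 13 of 15 lower, a median of -0.36 and 0 members passing (camera adjusted p = 8.39e-05, and adjusted p = 0.505 with an estimated correlation). NT5E, which makes adenosine, had -0.63 (287 ± 56.4 to 185 ± 67.8 CPM), the chemokine CCL5 -1.18, CXCL16 -0.45 and PVR -0.33. With 1 library left out, CCL5 ran from -1.96 to -0.89 and PVR from -0.43 to -0.15. The median was -0.19 without control replicate 4 and -0.57 without DDR1 replicate 2, and the call was lost without the 2 controls that have no lane (adjusted p = 0.0627, median -0.23). Without the 2 of lane 7 the median was -0.60.

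Cytosolic ribosomal protein genes rose as a list, with all 34 members higher, a median of 0.37, 8 members at an unadjusted p under 0.05 and 0 passing when adjusted over the list alone (camera adjusted p = 2.51e-17, and adjusted p = 0.430 with an estimated correlation). RPS23 (ENSG00000186468, chromosome 5, 82273358 to 82278577, minus strand) stood at 265 ± 44.4 CPM in controls and 400 ± 42.9 in the DDR1 group. RPL3 stood at 471 ± 53.5 and 695 ± 141 CPM, and RPS2 at 740 ± 132 and 1138 ± 299. The groups did not overlap for any of these 3 genes, and reads from their pseudogenes make single values uncertain. This list, the NF-kB list, the chemoattractant list, the interferon list and the T cell ligand list passed with each of the 8 libraries left out in turn. The other 8 called lists did not.

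**Figure D2:**
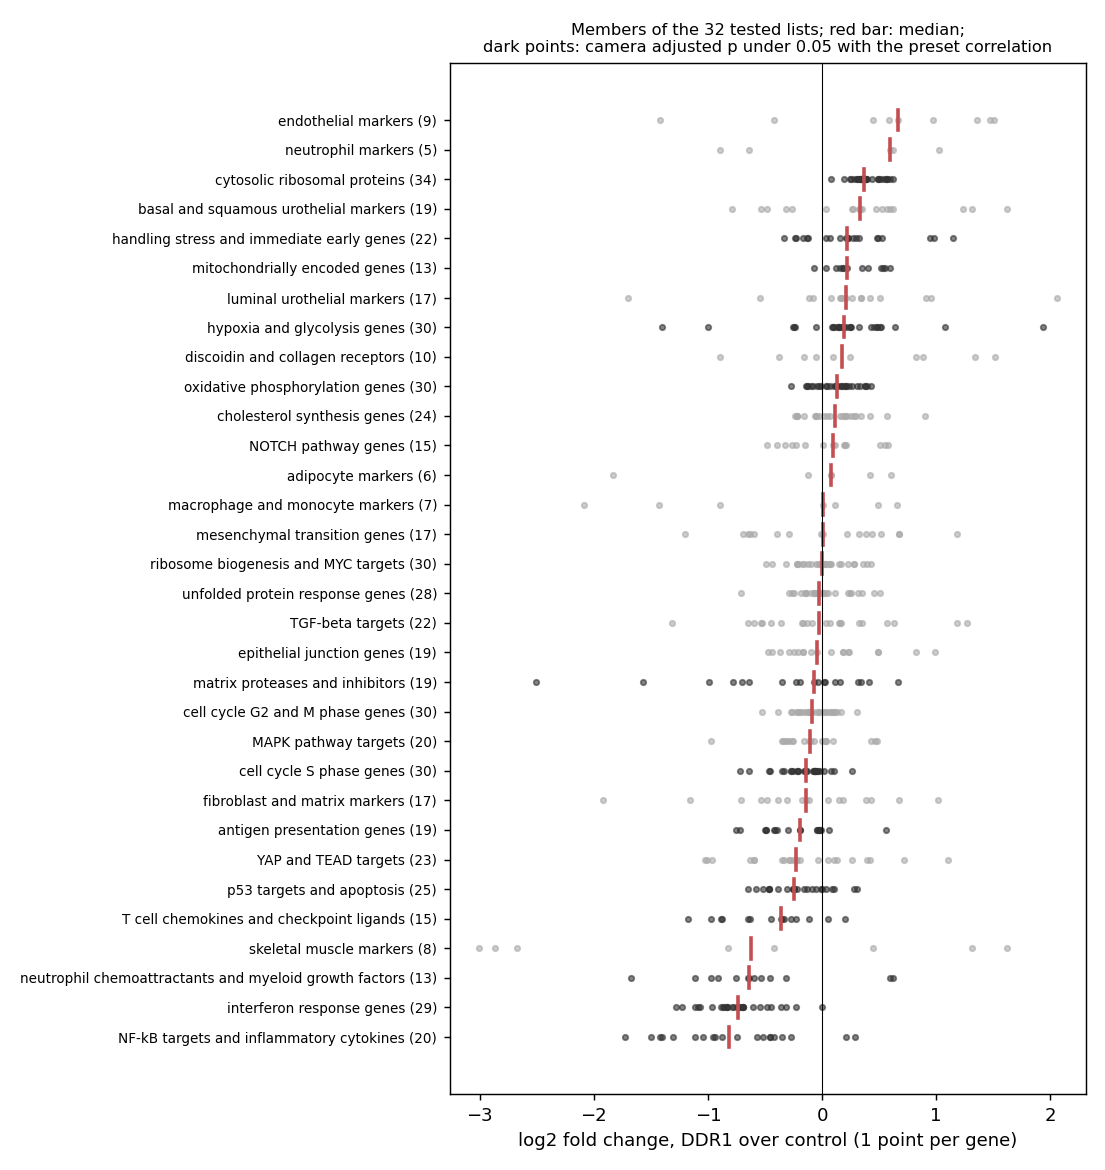
Log2 fold changes (DDR1 over control, horizontal axis) of the members of 32 lists, with 1 point per gene, the median as a red bar and the number of members in parentheses. Dark points mark the 13 lists that passed camera with the preset correlation, from the NF-kB list (median -0.81) to the ribosomal protein list (median 0.37).

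Among metabolic lists, hypoxia and glycolysis genes rose as a list, with 24 of 30 higher, a median of 0.19 and 0 members passing (camera adjusted p = 0.000468, and adjusted p = 0.655 with an estimated correlation). CA12, a carbonic anhydrase, had a log2 fold change of 1.93 (9.34 ± 2.89 to 35.8 ± 33.2 CPM; 1.14 without DDR1 replicate 4), the glycolytic genes ALDOA 0.51 and HK1 0.48, and BNIP3L 0.43. It was no longer called without control replicate 2 (adjusted p = 0.0883, median 0.08), control replicate 4 (0.0539) and the 2 controls that have no lane (0.327, median 0.05), or with library quality weights (0.406). The median was 0.42 without control replicate 1 and 0.41 without the 2 controls of lane 7. Nuclear oxidative phosphorylation genes rose as a list, with 21 of 30 higher, a median of 0.13 and 0 members passing (camera adjusted p = 0.0218, and adjusted p = 0.655 with an estimated correlation). CYC1 had 0.43 (52.5 ± 1.80 to 70.5 ± 28.4 CPM; 0.16 to 0.63 with 1 library left out), COX5A 0.39, NDUFB10 0.37 and COX6C 0.30. This list failed without control replicate 3 (adjusted p = 0.113), control replicate 4 (0.127), DDR1 replicate 2 (0.0583), the library labelled DDR1 replicate 1 (0.739, median 0.01) and the 2 controls that have no lane (0.734, median 0.06), and with library quality weights (0.0809). The median was 0.24 without DDR1 replicate 3 and 0.28 without the 2 controls of lane 7. The mitochondrially encoded genes rose as a list, with 12 of 13 higher, a median of 0.21 and 0 members passing (camera adjusted p = 0.00428, and adjusted p = 0.655 with an estimated correlation). MT-CO3 had 0.60 (2401 ± 840 to 3629 ± 608 CPM), MT-ATP8 0.55, MT-ATP6 0.53 and MT-CYB 0.40, and the gene models of MT-ATP6 and MT-ATP8 overlap. With 1 library left out, MT-ATP8 ran from 0.25 to 1.61, MT-ATP6 from 0.30 to 0.89 and MT-CYB from 0.21 to 0.73. The mitochondrial list was not called without control replicate 1 (adjusted p = 0.318, median 0.05), control replicate 4 (0.0593, median 0.14), DDR1 replicate 3 (0.133, median 0.04) and the 2 controls that have no lane (0.189, median 0.03), or with libraries of a shared title prefix summed (0.383, median -0.05). The median was 0.59 without control replicate 2, 0.34 without the library labelled DDR1 replicate 1 and 0.41 without the 2 controls of lane 7.

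Cell cycle S phase genes fell as a list, with 26 of 30 lower, a median of -0.14 and 0 members passing (camera adjusted p = 0.00166, and adjusted p = 0.655 with an estimated correlation). The ubiquitin ligase subunit DTL had -0.64 (41.6 ± 5.48 to 26.7 ± 7.43 CPM), cyclin E1 (CCNE1) -0.72, the ribonucleotide reductase subunit RRM2 -0.46 and CLSPN -0.46. The call was lost without DDR1 replicate 3 (adjusted p = 0.796, median 0.03), without the 2 controls of lane 7 (0.195, median -0.03) and with libraries of a shared title prefix summed (0.383, median -0.03). The median was -0.25 without the library labelled DDR1 replicate 1. p53 targets and apoptosis genes fell as a list, with 19 of 25 lower, a median of -0.24 and 0 members passing (camera adjusted p = 0.00874, and adjusted p = 0.541 with an estimated correlation). PMAIP1 had -0.52, the death receptor gene TNFRSF10B -0.46 (137 ± 30.3 to 99.1 ± 11.3 CPM) and BCL2L1 -0.31. The call was lost without control replicate 3 (adjusted p = 0.0676, median -0.15), the library labelled DDR1 replicate 1 (0.0875) and the 2 controls that have no lane (0.344, median -0.07), and with library quality weights (0.126). The median was -0.16 without control replicate 4. Matrix proteases and inhibitors passed in the lower direction with 11 of 19 members lower, a median of -0.07, a mean of -0.32 and 0 members passing (camera adjusted p = 0.0352, and adjusted p = 0.655 with an estimated correlation). MMP9 had -2.50 (3.58 ± 3.06 to 0.620 ± 0.588 CPM), MMP10 -1.57 (502 ± 263 to 169 ± 158 CPM), the urokinase receptor gene PLAUR -0.99 and urokinase (PLAU) -0.70. The call was lost without control replicate 1 (adjusted p = 0.0987), control replicate 2 (0.0510, median -0.19), control replicate 4 (0.121), DDR1 replicate 4 (0.418, median 0.01), the library labelled DDR1 replicate 1 (0.900, median 0.12), the 2 controls of lane 7 (0.195, median -0.13) and the 2 that have no lane (0.0797, median -0.26). It was also lost with DESeq2 (0.135), the 5 CPM filter (0.0737) and library quality weights (0.765, reversed). The median was -0.25 without control replicate 3, -0.43 without DDR1 replicate 2 and -0.40 without DDR1 replicate 3. With limma-voom over all libraries the list passed (camera adjusted p = 0.0465) and its median was -0.35. Handling stress and immediate early genes rose as a list, with 16 of 22 higher, a median of 0.22 and 0 members passing (camera adjusted p = 0.0445, and adjusted p = 0.655 with an estimated correlation). FOS had 0.95 (16.6 ± 6.90 to 32 ± 13.2 CPM), FOSB 1.14, NR4A1 0.98 and ZFP36 0.49. With 1 library left out, FOSB ran from 0.14 to 1.42 and NR4A1 from 0.44 to 1.29. The call was lost without control replicate 2 (adjusted p = 0.204), control replicate 4 (0.134), DDR1 replicate 4 (0.998, median -0.04), the 2 controls of lane 7 (0.195) and the 2 that have no lane (0.0819). The same held with limma-voom (0.0817), with library quality weights (0.524) and with libraries of a shared title prefix summed (0.0687, median 0.12). The median was 0.12 without control replicate 1.

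**Figure D3:**
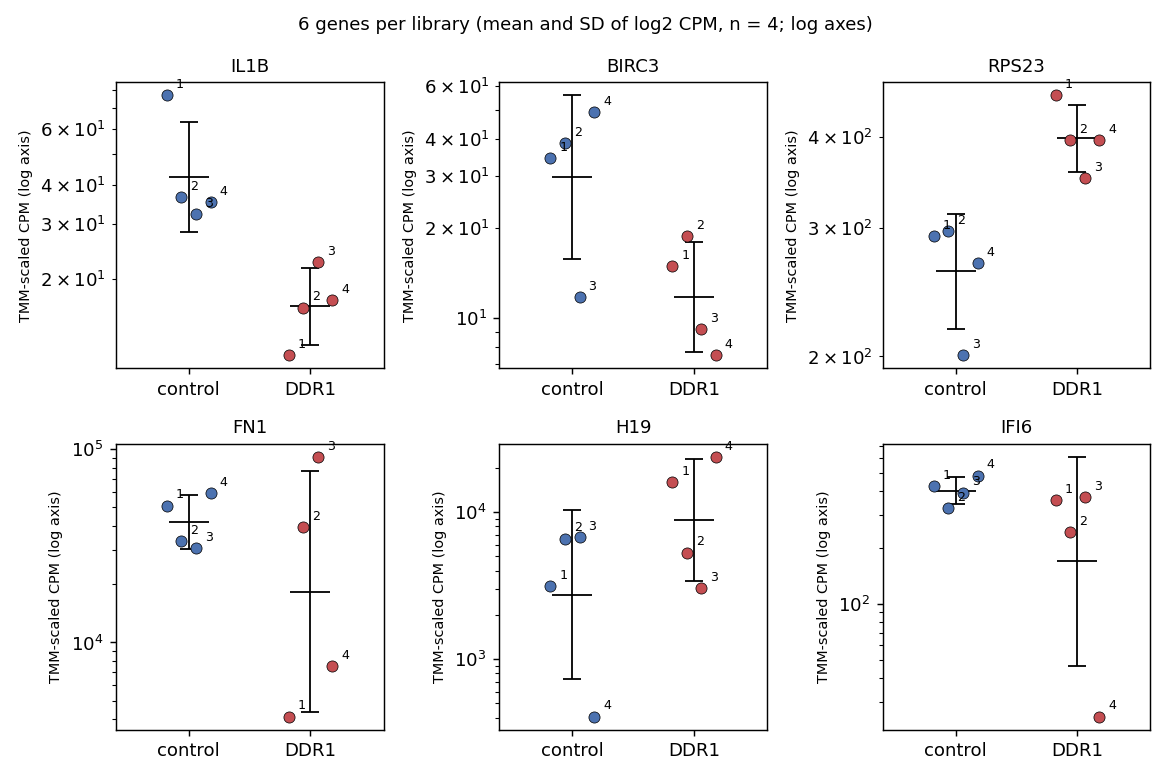
TMM-scaled CPM on log axes for 6 genes in each library, with the mean and SD of log2 CPM over 4 libraries as bars and replicate numbers beside the points. IL1B and RPS23 do not overlap between the groups, BIRC3 overlaps through control replicate 3 at 11.8 CPM, and FN1, H19 and IFI6, chosen after their values were seen, spread more widely within the DDR1 group than the other 3, with FN1 between 4133 and 91320 CPM in the DDR1 group.

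The other 19 tested lists did not pass camera. Among tumour programs, the adjusted p was 0.199 for luminal urothelial markers (median 0.21), 0.168 for basal and squamous urothelial markers (0.33), 0.340 for epithelial junction genes (-0.04) and 0.765 for mesenchymal transition genes (0.01). It was 0.0914 for MAPK pathway targets (-0.11), 0.0542 for YAP and TEAD targets (-0.23, and 0.03 without the library labelled DDR1 replicate 1), 0.199 for TGF-beta targets (-0.03) and 0.965 for NOTCH pathway genes (0.10). It was 0.199 for cell cycle G2 and M phase genes (-0.09), 0.968 for ribosome biogenesis and MYC targets (0.0033), 0.0818 for cholesterol synthesis genes (0.11) and 0.709 for unfolded protein response genes (-0.03). Of all 19, 14 passed when at least 1 particular library was left out, among them cell cycle G2 and M phase genes without the library labelled DDR1 replicate 1 (adjusted p = 0.000917, median -0.22).

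For markers of other cells, no list passed camera after edgeR's main filter over all 8 libraries. Endothelial markers passed with DESeq2 (0.0155) and with the 5 CPM filter (0.0320), macrophage markers with no filter on low counts (0.0371) and with libraries of a shared title prefix summed (0.00641), fibroblast markers with those summed (0.00166), and muscle markers with library quality weights (0.0275). These calls and those below used the preset correlation. With an estimated correlation in the main setting, the camera adjusted p was 0.655 for endothelial and muscle markers, 0.631 for macrophage markers and 0.704 for fibroblast markers. The adjusted p was 0.205 for fibroblast and matrix markers (17 entries tested, median -0.14), 0.0786 for endothelial markers (9, 0.66), 0.144 for macrophage and monocyte markers (7, 0.01), 0.474 for neutrophil markers (5, 0.60), 0.238 for skeletal muscle markers (8, -0.62) and 0.970 for adipocyte markers (6, 0.08). The macrophage list passed, in the lower direction, without DDR1 replicate 2 (0.00420, median -0.94), DDR1 replicate 3 (0.0134, median -0.38), DDR1 replicate 4 (0.0405, median -0.24) or control replicate 3 (0.0149, median -0.72). The fibroblast list passed, also lower, without DDR1 replicate 2 (0.0436, median -0.37), DDR1 replicate 3 (0.0249, median -0.46) or control replicate 3 (0.0263, median -0.05). Muscle markers passed, lower, without the library labelled DDR1 replicate 1 (0.0211, median -1.18), DDR1 replicate 4 (0.0291, median -0.51) or control replicate 3 (0.00513, median -0.74). Endothelial markers passed, higher, without the library labelled DDR1 replicate 1 (0.00217, median 0.92), and neutrophil markers, lower, without DDR1 replicate 2 (0.0133, median -1.20). Lymphocyte markers had 3 tested members (median -0.06) and erythroid markers 0, and neither list was tested. The most abundant members were COL6A1 with 535 ± 323 CPM in controls and 555 ± 544 in the DDR1 group, LAPTM5 with 153 ± 71.2 and 154 ± 67.3, TTN with 108 ± 30.5 and 80.8 ± 18.3, ENG with 40.2 ± 14.2 and 30 ± 12.6, S100A9 with 35.1 ± 40.5 and 53.2 ± 79.2, LCK with 8.53 ± 6.67 and 8.22 ± 8.07, and LIPE with 2.16 ± 1.13 and 2.29 ± 1.39. TTN overlaps 7 tested antisense genes, and without strand its reads cannot be told from theirs. For neutrophil markers the median was above 0 while the test pointed lower. The same held for macrophage and adipocyte markers, whose means were also below 0 (-0.45 and -0.13), and for mesenchymal transition genes. For epithelial junction genes the median and the test were lower while the mean was 0.06, and for unfolded protein response genes the test and the mean were higher while the median was lower.

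Because the lanes named in the titles differ between the groups, and 2 controls name none, the controls were also compared among themselves. Between the 2 controls without a lane in the title and the 2 of lane 7, edgeR called 0 genes, with 892 at an unadjusted p under 0.05. limma-voom called 0, DESeq2 called 15, and edgeR with no filter on low counts called 37, with 2157 at an unadjusted p under 0.05. The 2 controls without a lane are also the 2 controls that share a title prefix. The split therefore cannot tell lane from prefix. Recovery with 2 libraries against 2 was not simulated, so a count of 0 does not show that the controls are alike.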

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

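The tests of host macrophages, transcript length and GC content, a swap, a wrong label and the splits for genes and lists with edgeR and camera were chosen after the result was seen. The splits for DESeq2 and the NF-kB and ribosomal lists, and the tests of depth, were set before.

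For the count of genes with edgeR the splits say nothing, because a real count of 0 fixes the outcome. All 35 splits of the 8 libraries into 4 and 4 gave at least as many genes with edgeR as the real 0 (791 at an unadjusted p under 0.05), and the highest other split gave 1. More genes at an unadjusted p than the real split had came from 14 splits, up to 2448. Chance could not be excluded for the other 2 counts of calls. As many lists as the real 13 were called in 17 of 35 splits, with 19 in the highest other. As many genes as DESeq2's 16 were called in 16 of 35 splits, and the highest other split called 383. That split set control replicates 1 and 3 with the library labelled DDR1 replicate 1 and DDR1 replicate 4. It was picked as the highest, its count was not set against chance, and edgeR called 0 genes in it. Whether the samples hold a structure other than the groups was therefore not decided by the counts. The split puts 1 control of lane 7 and 1 without a lane on each side, so it does not follow the lane in the titles. On the leading principal component, control replicate 3, the library labelled DDR1 replicate 1 and DDR1 replicate 4 stood at 48.2, 74.2 and 55.7. Others lay from -52.6 to -20.7, so that component crosses the groups. The NF-kB list had its lowest mean log2 CPM in the same libraries (4.03, 3.43 and 3.76, others 4.21 to 5.21). So had the chemoattractant list (3.02, 2.33 and 2.42, others 3.32 to 4.22). The interferon list was highest in control replicate 3 (7.47).

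For the lower NF-kB and cytokine list, the first pattern weighed, the real split gave the smallest camera p with an estimated correlation of all splits (1 of 35; 0.0139, smallest other 0.0220), which is the lowest rank that 35 splits allow. It was 1 of 2 lists among 32 with this property, where chance gives 0.91, so chance is not excluded once the choice among lists is counted. Thinning every library to the total of the shallowest, 13716285 counts, left the median at -0.774 (-0.839 to -0.686 over 5 thinnings). Thinning keeps the expected share of each gene in its library, so the median could hardly move. The greater depth of the DDR1 libraries, and what goes with it, therefore stays undecided. Fewer host macrophages stay open: the 7 tested of 21 macrophage and monocyte markers had a median of 0.00745 with quartiles of -1.16 and 0.30, as CTSS (24.8 to 9.19 CPM) and CD68 (19 to 30 CPM) went apart while LAPTM5 stood at 153 and 154 CPM, and that median was -0.94 without DDR1 replicate 2, -0.72 without control replicate 3 and -0.38 without DDR1 replicate 3. The lanes named in the titles (8 for the DDR1 group, 7 for 2 controls, none for 2) leave lane open, and an effect of DDR1 on these genes also remains open.

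The higher ribosomal protein list was the second pattern. The real split again gave the smallest p of all (1 of 35; 0.0269, smallest other 0.0600), and again chance is not excluded once the choice among 32 lists is counted. Thinning left the median at 0.374 (0.367 to 0.379), but it keeps the expected share of each gene and so does not decide on depth. It was set among 10000 random lists matched on transcript length (median 741 against 714), GC content and, less closely, mean expression (median log2 CPM 8.20 against 8.82). The list's median of 0.37 lay at percentile 100, where the central 95% ran from -0.07 to 0.09. The matched lists had a median of 0.03, so genes alike in these properties did not share the shift, which argues against a bias by them. Matched genes were drawn singly, while the estimated correlation within the ribosomal list was 0.344. The percentile therefore does not measure chance. RNA quality, reads of pseudogenes and lane were not separated from the group by any value here, and an effect of DDR1 remains open.

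The low DDR1 level in the library labelled DDR1 replicate 1 (159 CPM) was the third pattern. The bound written against a swap with a control library was met. The lowest of the other 3 DDR1 libraries (343 CPM) lay 133 CPM above the highest control (210 CPM), more than the SD of the controls of 42.3 CPM. That bound cannot exclude a swap with the highest control, replicate 3, because the groups would then not overlap in DDR1. Control replicate 3 was also the library best correlated with the one labelled DDR1 replicate 1 (0.954). A swap therefore stays undecided. A single wrong label could not be decided either: the library labelled DDR1 replicate 1 correlated with the controls at 0.916 to 0.954 and with the other DDR1 libraries at 0.917 to 0.947, and only 4 of the other 7 libraries correlated best with a library of their own group. Loss of the expression construct in that tumour may be an explanation and was not tested. The library labelled DDR1 replicate 1 is also the only DDR1 library with its title prefix. Its low level therefore cannot be told apart from a difference between prefixes.

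Of 202 groups of 4 values, 15 held a library that lay far from the other 3, each time above them. A rate of 1 in 20 would give 10.1, but that rate holds for independent values with a normal spread. CPM entered without logs and the groups share libraries, so the 15 cannot be set against chance. DDR2 in DDR1 replicate 3 was 2.91 CPM (others 1.35 to 1.61). IL1B in control replicate 1 was 76.9 CPM (32.2 to 36.4), so the controls' mean leans on it. HLA-C in the library labelled DDR1 replicate 1 was 142 CPM (87.8 to 95.1). BNIP3L in DDR1 replicate 3 was 157 CPM (118 to 124), MT-ATP8 in control replicate 2 was 142 CPM (18.4 to 31.6), and RPL3 in control replicate 3 was 551 CPM (441 to 450). RPS2 in DDR1 replicate 4 was 1586 CPM (984 to 996), FOSB there was 125 CPM (18.2 to 35.6), ZFP36 36.9 CPM (12.2 to 14.6), COL6A1 1363 CPM (194 to 384) and LCK 20.2 CPM (2.59 to 5.06). FOS in control replicate 1 was 26.9 CPM (12.5 to 14.3), and S100A9 in DDR1 replicate 2 was 171 CPM (0.750 to 22.3). The mean log2 CPM of T cell chemokines and checkpoint ligands in control replicate 4 was 5.16 (4.20 to 4.31). Control replicate 2 had 35208 genes with counts (28259 to 28823).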

How the results depend on the processing

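The tests on protein-coding genes only and with library quality weights were chosen after seeing the data. Over 12 alternatives besides leaving out 1 library, the DDR1 level ran from 1.17 to 1.81 and passed in 11; without the controls of lane 7 it was 1.31, with an unadjusted edgeR p of 0.0653. With 1 library left out it ran from 1.05 to 1.79. The count of genes changed by DDR1 overexpression with edgeR (0, with 791 at an unadjusted p under 0.05) was 0 in 12 of 13 such alternatives and with each library left out, and 16 with DESeq2. The count of gene lists, 13, was 0 with an estimated correlation, 0 with fry, 6 without the controls that have no lane, and 8 (without control replicate 4) to 18 (without DDR1 replicate 4) with 1 library left out; the other alternatives gave 11 to 17. Between the controls with and without a lane, 0 genes became 15 with DESeq2 and 37 with no filter. No paired analysis was possible because the replicate numbers follow accession order only. The simulated recovery was 9% for 2-fold and 54% for 4-fold changes, so a count of 0 leaves room for changes of either size. The cause of each change in this part was not tested, except that settings with fewer libraries have fewer degrees of freedom.

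Of the values of named genes under other settings, 753 were the same, 17 reversed and 1 was stronger (IL1B with DESeq2); of list values, 319 were the same, 49 weaker, 23 stronger and 21 reversed. With 1 library left out, 464 gene values were the same and 16 reversed, and 178 list values were the same, 30 stronger, 21 weaker and 27 reversed. Reversals concerned values that had not passed, apart from the protease and handling stress lists. For COL6A1 the log2 fold change was -0.18 with limma-voom, -0.18 with limma-trend, -0.37 with quality weights, -0.20 without the controls that have no lane and -0.54 with libraries of a shared title prefix summed. For LAPTM5 it was -0.0033 with upper quartile scaling, -0.00039 with limma-voom, -0.0042 without the controls that have no lane and -0.24 with summed libraries. For S100A9 it was -0.23 with limma-voom, -0.26 with limma-trend and -0.22 without the controls that have no lane. In that last setting DDR2 was 0.069 and HLA-C 0.035. Without the controls of lane 7, LCK was 0.99 and LIPE -0.36, and LIPE was -0.072 with quality weights. Among list medians, where the direction is that of camera, epithelial junction genes had -0.039 with DESeq2, 0.26 without the lane 7 controls, 0.26 with summed libraries and 0.085 with quality weights. Ribosome biogenesis genes had -0.025 with limma-voom, -0.0056 with the 5 CPM filter, 0.0033 with fry and -0.031 without the controls that have no lane, where basal markers had -0.23 and adipocyte markers 0.026. Without the lane 7 controls, mesenchymal genes had 0.30, G2 and M phase genes 0.088, unfolded protein response genes -0.020, NOTCH genes 0.15 and neutrophil markers 2.36. G2 and M phase genes had 0.015 with summed libraries. With quality weights, matrix proteases had 0.090, unfolded protein response genes -0.032, NOTCH genes 0.0084, neutrophil markers 1.93 and adipocyte markers 0.40.

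With 1 library left out, these values ran from -0.89 to 0.53 for COL6A1, -0.23 to 0.28 for LAPTM5, -1.34 to 1.77 for S100A9, -1.01 to 0.61 for LCK, -0.40 to 0.49 for LIPE and -0.012 to 0.66 for ZFP36. List medians ran from -0.050 to 0.18 for NOTCH genes, -0.29 to 0.036 for TGF-beta targets, -0.093 to 0.32 for adipocyte markers, -0.41 to 0.78 for basal markers, -0.22 to 0.059 for G2 and M phase genes, -0.18 to 0.21 for epithelial junction genes, -0.46 to 0.11 for fibroblast markers, -0.043 to 0.29 for handling stress genes, -0.63 to 0.41 for mesenchymal genes, -1.20 to 1.77 for neutrophil markers, -0.10 to 0.11 for ribosome biogenesis genes and -0.064 to 0.026 for unfolded protein response genes. The median also crossed 0, while the direction of camera stayed, for receptors (-0.57 to 0.59), YAP targets (-0.38 to 0.03), macrophage markers (-0.94 to 0.18), S phase genes (-0.25 to 0.03) and matrix proteases (-0.43 to 0.12).

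Lists that had not passed gained a camera call with the preset correlation (adjusted p in parentheses) as follows. Without the library labelled DDR1 replicate 1 these were receptors (0.00146), epithelial junction genes (0.00187), G2 and M phase genes (0.000917), endothelial markers (0.00217) and muscle markers (0.0211). Without DDR1 replicate 2 they were YAP targets (0.0323), fibroblast (0.0436), macrophage (0.00420) and neutrophil markers (0.0133). Without DDR1 replicate 3 they were luminal markers (0.00582), cholesterol synthesis genes (0.00871), YAP targets (0.0249), TGF-beta targets (0.00856), fibroblast (0.0249) and macrophage markers (0.0134). Without DDR1 replicate 4 they were receptors (0.0166), basal markers (0.0117), MAPK targets (0.0125), G2 and M phase genes (0.0139), YAP targets (0.0153), macrophage (0.0405) and muscle markers (0.0291). Without control replicate 3 they were G2 and M phase genes (0.0245), YAP targets (0.0177), fibroblast (0.0263), macrophage (0.0149) and muscle markers (0.00513). Cholesterol synthesis genes passed without control replicate 1 (0.00835), basal markers without control replicate 2 (0.00452) and receptors without control replicate 4 (0.0261). With all libraries, receptors passed with DESeq2 (0.0432), no filter (0.0143) and the 5 CPM filter (0.0179), endothelial markers with DESeq2 (0.0155) and the 5 CPM filter (0.0320), and luminal markers with the 5 CPM filter (0.00781). No filter added cholesterol synthesis genes (0.0283), YAP targets (0.0498) and macrophage markers (0.0371), and the 5 CPM filter YAP targets (0.00651). Without the controls that have no lane, G2 and M phase genes passed (0.00322), and without those of lane 7, basal markers (0.000143) and cholesterol synthesis genes (0.0129). Summed libraries added luminal markers (0.00645), mesenchymal genes (0.0217), MAPK targets (0.0217), YAP targets (0.00432), TGF-beta targets (0.00968), fibroblast (0.00166) and macrophage markers (0.00641). Quality weights added basal markers (0.000548), G2 and M phase genes (0.000156) and muscle markers (0.0275).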

Other observations

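The test below of expression against the measured DDR1 level was set before its result was seen, the simulation beside it after, and the genes named here were chosen after their values were seen. FN1, which encodes fibronectin and took up to 8.5% of all counts of a library, stood at 50977, 33448, 30841 and 59101 CPM in control replicates 1 to 4, and at 4133, 39582, 91320 and 7538 CPM in DDR1 replicates 1 to 4, of which the lowest is the library labelled DDR1 replicate 1. THBS1, thrombospondin, ran from 193 to 1228 CPM in controls and from 26.0 to 3327 CPM in the DDR1 group. VCAM1 ran from 20.5 to 549 CPM and from 6.85 to 481 CPM, the matrix gene TNC from 128 to 1537 CPM and from 177 to 1915 CPM, and MGP from 5.68 to 282 CPM and from 2.04 to 610 CPM. The imprinted RNA H19 ran from 406 to 6734 CPM in controls and from 3032 to 23767 CPM in the DDR1 group, and its log2 fold change of 1.51 had a standard error of 0.84. CDH1, E-cadherin, ran from 23.7 to 120 CPM and from 3.65 to 167 CPM, the basal keratin KRT14 from 57.2 to 881 CPM and from 159 to 2471 CPM, and the mucin MUC16 from 39.1 to 1072 CPM and from 21.2 to 1040 CPM. KRT5 stood at 2013 ± 912 CPM in controls and 2785 ± 982 in the DDR1 group (SD, n = 4).

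Of the 29 interferon response genes tested, 26 had their lowest level in DDR1 replicate 4; ISG15 and IRF7 had it in control replicate 2 and ISG20 in the library labelled DDR1 replicate 1. IFI6 held 24.9 CPM in DDR1 replicate 4, against 242 to 485 CPM in the others, IFI44L 20.6 CPM against 291 to 607 CPM, MX1 24.4 CPM against 168 to 677 CPM, and IFIT1 22.3 CPM against 152 to 535 CPM. The mean log2 CPM of the whole list was 4.46 in that library and 6.15 to 7.47 in the other 7. This library also had the highest DDR1 level, 810 CPM. It was highest too in the share of mitochondrial ribosomal RNA (1.73%, others 0.08% to 0.53%) and in the mean of handling stress genes (5.77, others 4.80 to 5.08). DDR1 replicates 2 and 3, with DDR1 at 343 and 427 CPM, had interferon list means of 6.21 and 6.30, above control replicate 2 at 6.15.

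A response graded by the measured DDR1 level was tested as a hypothesis over the 8 libraries. Besides DDR1, 0 genes had an adjusted p under 0.05 in edgeR against log2 DDR1, with 1303 at an unadjusted p under 0.05. In 50 shuffles of the levels, 10 gave as many at an unadjusted p, up to 3810. The bound written in advance took 0 genes as evidence against a graded response. That bound was wrong, because this regression on simulated counts recovered only 5% of 100 genes with a slope of 0.5 (log2 expression per log2 DDR1) and 54% of 100 with a slope of 1, with 2 false calls. The hypothesis therefore stays undecided, above all for slopes as low as 0.5.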
